A study of Mus musculus with 2 samples.

How the data were processed

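Gene expression was measured in the gastrocnemius of control mice and of mice with a plaster cast, with 1 array per group. The labels give N = 6 for each group and say that samples were pooled, read here as RNA of 6 mice in each pool. Per the labels' protocols, total RNA was purified with a column kit, and Cy3-labelled cRNA was hybridised. The arrays were 1-colour Agilent whole mouse genome arrays with probe coordinates on the mm9 assembly, per the file headers. Both arrays were on 1 slide and share 1 scan time in the headers, so slide and scan do not differ between the groups, while position on the slide does.

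The spot intensities were extracted with Agilent Feature Extraction 9.5, per the submitters' processing notes. Per the file headers, the processed intensity of a spot is its mean brightness after background subtraction and spatial and multiplicative detrending within the array, with a surrogate value in place of a signal too close to background, and it is not normalized between arrays. The deposited table of the whole series holds a linear intensity as well. It was found by comparison to be the processed signal divided by the array's 75th percentile over all 44397 spots and multiplied by 100. Its columns had medians of 9.00 for control and 8.70 for cast, and 54.9% of its values were whole numbers, rounded from that value. Elsewhere it matched to within 0.000033. Its scale, centring and direction are thus known, and the rounding is why it served as an alternative only. All columns of that table belong to the 2 samples.

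The processed signal was log2-transformed, and replicate spots of a probe were averaged. Control spots and the spots with a non-uniformity flag (2 on the control array, 9 on the cast array) were left out. Each array's 75th percentile over its non-control probes, 385 in control and 486 in cast, was subtracted on the log2 scale. A gene was measured when 1 of its probes was well above background on both arrays, by the scanner software's flag on more than 0.5 of its spots. Its value was that of the probe with the highest mean signal. Of 3491 genes with several such probes, the median SD between probes was 0.12 log2 units. Of 113 genes with several probes and at least a 2-fold difference, 105 had all probes in the same direction.

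Probes were named through their accession without its version where the reference gene table (assembly GRCm38, used for names alone) held it, which was so for 26055 of 39429 probes. Otherwise the name on the array was kept, and 3358 names were updated by the accession. A symbol was available for 32552 probes, and 6877 had none. Probes of close relatives can share signal, such as Mt1 and Mt2, the globins, the myosin heavy chains, the actins Actc1 and Acta1, Amd1 and Amd2, and ribosomal protein genes with their processed copies, so their values are less certain than the spot-level SD shows. The array measures with a single probe for most genes, and a probe can miss a transcript with another 3' end.

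With 1 pooled array per group there is no replicate check and no test. Sizes are given instead, with a 2-fold threshold for counts. The spot-level SD of a log2 ratio was taken from the SD between spots of 262 replicated probes within each array, added up as if the arrays were independent, with a median of 0.10. The 7 spike-in controls with every spot above background on both arrays had a mean log2 ratio of -0.35 and an SD of 0.04 after scaling. Over 10 equal parts of the array, the median log2 ratio of single spots ranged from -0.04 to 0.0031 from top to bottom and from -0.03 to 0.03 from side to side. Over 10 parts by signal it ranged from -0.11 to 0.07.

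Gene lists were 44, with 1016 entries, of which 1005 were on the array and 927 measured. For each, the median log2 ratio was set beside those of 10000 random lists of as many genes, matched on mean signal in 20 bins and drawn with replacement. A list stood apart when its percentile lay in the outer 2.5% on either side and it had at least 5 measured members. This describes these 2 arrays, and genes of a list are not independent, so percentiles are not p-values. Where a gene was well above background on 1 array only, its fold was taken as a bound. It sets the bright value against the higher of the lowest signal among probes well above background on the other array and the dim probe's own, both normalized. Where the dim probe's own is the higher, the fold is a plain ratio and not a limit. The spot-level SD does not enter it.

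The lists, the thresholds, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 genes with the highest and the 12 with the lowest log2 ratio among genes with a symbol, measured on both arrays, with a mean level at or above the median of measured genes and all probes in the same direction, passing over clone-like and predicted names (0 among the highest, 1 among the lowest). It took up to 4 members of each list with the largest absolute log2 ratio, and up to 4 genes per direction with the largest bound. It also took 22 genes whatever their values, namely Fbxo32, Trim63, Fbxo30, Foxo1, Foxo3, Mstn, Igf1, Ppargc1a, Myog, Chrna1, Cdkn1a, Gadd45a, Dnmt3a, Gdf5, Bcat2, Glul, Myh7, Myh2, Myh1, Myh4, Actb and Gapdh.

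The alternatives were scaling by the median, by quantile normalization, by cyclic loess on signal, by the 75th percentile of probes above background on both arrays, by the spike-ins, and none. Others were normexp background correction with an offset of 50, the deposited series table, 3 other filters on dim probes, the mean of a gene's probes, outlier spots kept, and thresholds of 1.5-fold and 3-fold. For the lists, random lists were also drawn unmatched, the largest member or members shared between lists were left out, and the outer bounds were set to 0.5%.

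The code was tested on simulated data. Both a control and a cast array were simulated, each as the mean of the 2 real arrays plus noise of about the spot-level SD. The simulated cast array had a shift of 0.3 on all genes, and 200 of 15050 genes were changed. All 50 genes changed 1.5-fold, 2-fold, 3-fold or 4-fold, each, were given the right direction. Of the 14850 unchanged genes, 0 reached 2-fold, and their median log2 ratio was -0.0016. This noise leaves out the spread between pools and hybridisations. The 0 is therefore no rate of false calls for the real arrays. All 50 genes changed 3-fold and all 50 changed 4-fold passed the 2-fold threshold, against 21 of 50 changed 2-fold. Of 200 random lists of 20 genes, 5.0% lay beyond the outer bounds, and all 20 lists moved by 0.5 log2 units lay above the upper one. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for quantile, loess and normexp.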

Results

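The gastrocnemius, the main calf muscle, was compared between male C57BL/6 mice whose hindlimb had been held still in a plaster cast for 11 days and control mice of the same age, 9 weeks. A cast stops a limb from being used and loaded, and the title of the series describes the muscle as atrophied. RNA was pooled within each group, from 6 mice as the labels are read here, and each pool was labelled with Cy3 and hybridised to 1 whole-genome mouse array. Each group was therefore n = 1 array, with no replicate, and no value has a p-value or an SE. The differences describe these 2 pools, and the number of arrays limits the precision.

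Of 39418 probes with a value, 23896 (60.6%) were well above background on the control array and 22373 (56.8%) on the cast array. The lowest signal called well above background was 13.1 on the control array and 20.3 on the cast array, so dim genes were called less easily on the latter. No gene spot was saturated. A probe well above background on both arrays was found for 15050 genes. Replicate spots of a probe gave a spot-level SD of the log2 ratio of 0.16 for the 66 dimmest replicated probes and of 0.08 for the 66 brightest. This SD covers the error of single spots, and neither the spread between mice nor that between hybridisations.

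Which transcripts differed between cast and control muscle is the question the design puts. Sarcolipin (Sln), a small inhibitor of the calcium pump of the sarcoplasmic reticulum, had the largest difference and was 64.5-fold higher on the cast array. Cpne2, a calcium-dependent membrane-binding protein, was 15.1-fold higher, and Ankrd1, an ankyrin repeat protein of the sarcomere and nucleus, was 14.5-fold higher. The largest difference in the other direction was that of cardiac alpha-actin (Actc1), which was 13.8-fold lower. Across all 15050 genes, 336 were at least 2-fold higher on the cast array and 316 at least 2-fold lower, together 4.33% of the genes. At least 4-fold differences were held by 58 genes that were higher and 19 that were lower.

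These directions are relative to the 75th percentile of each array. The median log2 ratio of all genes was -0.03 with this scaling. It was 0.31 with no scaling and 0.32 when the arrays were scaled on the spike-in controls, a shift of 0.34 and 0.35. The split then became 826 higher and 119 lower with no scaling, and 855 higher and 117 lower with spike-in scaling, while median scaling gave 397 and 254. Log2 ratios are log2(cast/control) under the 75th percentile scaling.

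**Figure D1:**
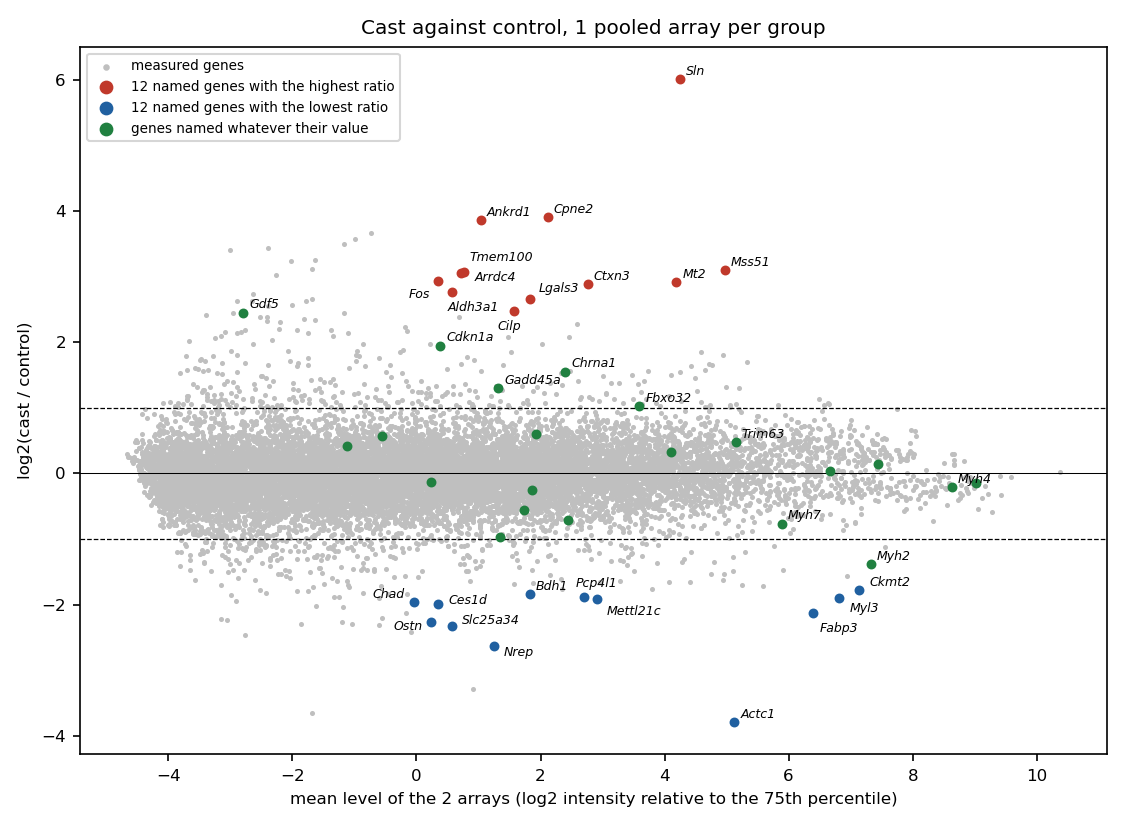
Log2(cast/control) of each measured gene against its mean log2 level over the 2 arrays, with dashed lines at 2-fold. Coloured points are named genes, with Sln highest at 6.01 and Actc1 lowest at -3.79.

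The other genes among the 12 highest were Mss51, a mitochondrial protein of skeletal muscle (8.56-fold higher), Arrdc4, an arrestin-domain protein (log2 ratio 3.07), Tmem100 (3.05), the immediate early factor Fos (2.93), the metallothionein Mt2 (2.92), Ctxn3 (2.88), the aldehyde dehydrogenase Aldh3a1 (2.77), galectin-3 (Lgals3, 2.66) and the cartilage matrix protein Cilp (2.48). The second, dimmer probe of Arrdc4 gave only 0.50, and that of Aldh3a1 gave 4.69. The 12 highest and the 12 lowest were taken among genes at or above the median level. Dimmer genes such as Krt18 (3.58) and Kera (-2.41) are outside these rankings. The 12 lowest held, after Actc1, Nrep (-2.62), the mitochondrial carrier Slc25a34 (-2.33), the secreted peptide osteocrin (Ostn, -2.26), the fatty acid binding protein Fabp3 (-2.13), the carboxylesterase Ces1d (3.99-fold lower), the cartilage matrix protein Chad (-1.97), the lysine methyltransferase Mettl21c (-1.91), the slow myosin light chain Myl3 (-1.90), Pcp4l1 (-1.89), the ketone body enzyme Bdh1 (-1.84) and mitochondrial creatine kinase (Ckmt2, -1.78). Each of these 24 genes stayed at least 2-fold apart in the same direction under every alternative scaling, background correction, filter and probe rule that was run.

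On the mm9 assembly, the Sln probe lies on chromosome 9 from 53701574 to 53701633, the Ankrd1 probe on chromosome 19 from 36186809 to 36186868, and the brighter Cpne2 probe on chromosome 8 from 97094199 to 97094258. The Actc1 probe lies on chromosome 2 from 113873064 to 113873123 and the Nrep probe on chromosome 18 from 33597298 to 33597357. Whether these probes lie in coding or untranslated exons was not looked up, because no gene models on mm9 were used here.

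Genes of muscle protein breakdown were next. Fbxo32 (atrogin-1), a muscle ubiquitin ligase, was 2.04-fold higher on the cast array, and Trim63 (MuRF1) was 1.39-fold higher. Proteasome subunit genes were higher as a group, with 30 of 34 above 0. The list of ubiquitin ligases and ubiquitin as a whole did not stand apart. Its median log2 ratio was 0.08, at percentile 75.95 of the matched random lists, with 1 of 18 members at least 1.5-fold higher and 0 lower. With the mean of probes the median of this list was -0.05, at percentile 29.0. Fbxo30 was at 0.57. The proteasome median was 0.39, above all 10000 random lists, with 8 of 34 subunits at least 1.5-fold higher. Psmd4, Psmd2, Psma7 and Psmb4 had log2 ratios of 1.13, 0.87, 0.87 and 0.78.

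Autophagy and lysosome genes had a median of 0.23, at percentile 99.3, with 17 of 28 above 0. Map1lc3a, a ubiquitin-like protein of the autophagosome membrane, was at 1.66, cathepsin L (Ctsl) at 0.72, calpain 2 (Capn2) at 0.67 and the muscle calpain Capn3 at -0.78. FoxO factors and their targets went both ways around a median of -0.02 (percentile 42.6), and that median crossed 0 under median, loess, spike-in and no scaling. Of 17 members, 4 were at least 2-fold higher, namely the cell cycle inhibitor Cdkn1a (1.95), the mTOR inhibitor Ddit4 (1.46), Gadd45a (1.30) and the translation repressor Eif4ebp1 (1.25). Foxo1 was at 0.60, and Foxo3 was not well above background on either array.

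In the IGF1, insulin and mTOR list, 7 of 20 members were above 0 and the median was -0.11 (percentile 15.1), which lay above 0 with no scaling or spike-in scaling. Igfbp3, Akt1, Igfbp5 and Igfbp6 had log2 ratios of 0.96, 0.85, -0.84 and -0.69. Igf1 itself was at -0.13, with 5 probes from -0.26 to 0.04, and became 0.21 with no scaling and 0.22 with spike-in scaling. Among genes of myostatin, activin and BMP signalling, the median was 0.03 (percentile 76.2). The growth factor Gdf5 was 5.47-fold higher, a log2 ratio of 2.45 from a dim probe that was 1.12 with normexp background correction, while Bmp7 was at -1.63, Id2 at 0.76 and Gdf11 at -0.63. Myostatin (Mstn) was at -0.25, and at 0.09 with no scaling and 0.10 with spike-in scaling.

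**Figure D2:**
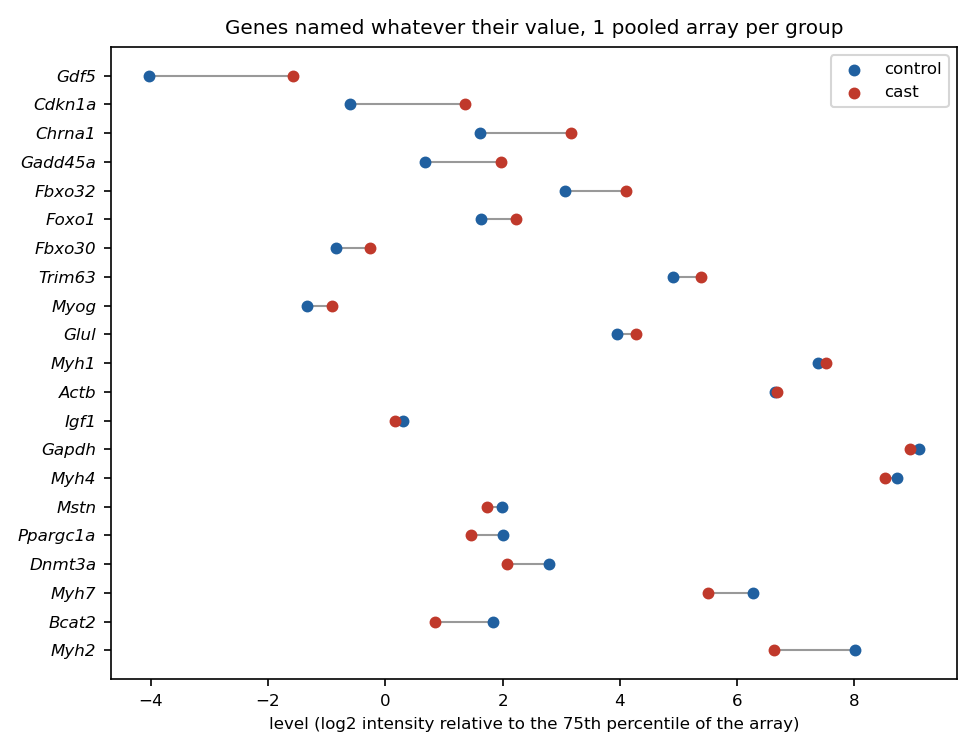
Levels of the 21 measured genes that were to be named whatever their value, as log2 intensity relative to the 75th percentile of each array, with 1 control point and 1 cast point per gene. Gdf5 had the largest difference, at 2.45, or 1.12 with normexp, where Cdkn1a exceeded it, and Myh2 the most negative, at -1.38.

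Genes of the neuromuscular junction and of denervated muscle were higher on the cast array for a part of the list. The acetylcholine receptor subunits Chrnb1 and Chrna1 were at 1.98 and 1.55, and the transcription factor Runx1, which denervation induces, was at 3.23. With Sln and Ankrd1, these were the 5 members at least 2-fold higher. The median over 23 members was 0.19 (percentile 98.8), and 9 members were below 0. Among the brighter genes alone, the median of the list was 0.79. Myogenin (Myog), a myogenic factor that denervation also induces, was at 0.42. Myogenic factors and satellite cell markers had a median of 0.08 (percentile 83.9), with 13 of 18 above 0, and among the brighter genes the median was 0.39 and stood apart (percentile 99.05). Cdh15 was at 1.35, desmin (Des) at 0.73, Vcam1 at -0.72 and Myf6 at 0.72.

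Contractile genes of slow fibres were lower on the cast array. The slow myosin light chains Myl3 and Myl2 were at -1.90 and -1.72, the muscle LIM protein Csrp3 at -1.55, and the slow myosin heavy chains Myh7b and Myh7 at -0.98 and -0.77. Of 15 members, 12 were below 0, and the median of -0.77 was below all 10000 random lists. Among the fast myosin heavy chains, Myh2 of oxidative fast fibres was 2.60-fold lower, Myh1 was 1.11-fold higher and Myh4, that of the fastest glycolytic fibres, was at -0.21, which turned to 0.13 with no scaling and 0.14 with spike-in scaling. The fast-fibre list had a median of -0.16 (percentile 5.58), which was 0 with quantile scaling. Its sign turned with no scaling and spike-in scaling, at 0.18 and 0.19. Besides Myh2, its most distant members were Mybph (-0.87), fast troponin I (Tnni2, -0.59) and calsequestrin 1 (Casq1, -0.41).

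Embryonic and perinatal sarcomere genes differed in direction. Actc1 was at -3.79, while cardiac troponin T (Tnnt2) was at 1.85, the embryonic light chain Myl4 at 1.24 and Mylk4 at -0.45. Their median was -0.04 (percentile 39.7), above 0 with median, spike-in and no scaling. The 5 members among the brighter genes had a median of -0.37 and stood apart as lower. The list of sarcomere scaffold, costamere and dystrophin genes had a median of 0.25 (percentile 98.9) but was split, with 13 members above 0 and 12 below. Its median was 0.06 without its largest member, where it no longer stood apart, and -0.01 with the mean of all probes. Xirp1 was at 1.25, Des at 0.73, integrin alpha 7 (Itga7) at 0.69 and dystrophin (Dmd) at 0.67. Excitation-contraction coupling genes had a median of -0.0043 (percentile 39.2), above 0 with median, quantile, spike-in and no scaling. The highest member of the list was Mss51, described above as a mitochondrial protein and not as a part of the coupling itself. The calcium channel subunit Cacng1 was at 1.66, Sypl2 at -1.47 and junctophilin 2 (Jph2) at -1.04.

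Genes of oxidative metabolism were lower on the cast array across several lists. All 25 fatty acid uptake and oxidation genes were below 0, with a median of -0.63, below all 10000 random lists. Fabp3, Acaa2, lipoprotein lipase (Lpl) and Hadhb had log2 ratios of -2.13, -1.49, -1.35 and -1.20. All 21 genes of the citric acid cycle list were below 0 as well, with a median of -0.36. This list also held subunits of pyruvate dehydrogenase such as Dlat, the pyruvate carriers and the cytosolic enzyme Mdh1. Isocitrate dehydrogenase 2 (Idh2) was at -1.47, Dlat at -0.82, Suclg1 at -0.74 and Mdh1 at -0.66. With no scaling or spike-in scaling these medians stayed below 0, at -0.29 and -0.28 for the fatty acid list and at -0.03 and -0.02 for the citric acid cycle.

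Of 77 respiratory chain and ATP synthase genes, 72 were below 0, and 9 were at least 1.5-fold lower against 0 higher. The median of -0.32 lay below all 10000 random lists, and became 0.02 with no scaling and 0.03 with spike-in scaling, so the group was lower relative to other genes rather than on every scale. Cox7a1, Ndufab1, Ndufs1 and Ndufc1 had log2 ratios of -1.12, -1.10, -0.84 and -0.71. Regulators of mitochondrial biogenesis had a median of -0.33 (percentile 0.05), and of 0.0073 and 0.019 with no scaling and spike-in scaling. Ppara was at -1.33, Esrrb at -1.21, Perm1 at -1.07 and Esrrg at -1.02, and the coactivator Ppargc1a was 1.47-fold lower.

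Glycolysis and glycogen genes had a median of -0.12 (percentile 5.46), above 0 with no scaling or spike-in scaling. The heart-type lactate dehydrogenase subunit Ldhb was at -1.54, Fbp2 at -0.74, the muscle phosphoglycerate mutase Pgam2 at -0.72 and the glycogen branching enzyme Gbe1 at 0.58. Gapdh, often used as a reference gene, was at -0.15, and lay above 0 with quantile, spike-in and no scaling, while 1 of its 7 probes gave 0.30. Beta-actin (Actb) was at 0.04 and lay below 0 with quantile and loess scaling, and its dimmer probe gave -0.51.

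Transcripts of enzymes that break down branched-chain amino acids were lower on the cast array. Of 21 genes, 19 were below 0 and 6 were at least 1.5-fold lower, and the median of -0.42 lay below all 10000 random lists, but was close to 0, at -0.08 and -0.07, with no scaling and spike-in scaling. The mitochondrial aminotransferase Bcat2 was at -0.98, Acad8 at -0.90, Mccc1 at -0.86, with probes that differed in sign, and the dehydrogenase subunit Dbt at -0.84. Glutamine synthetase (Glul) was at 0.33. Targets of ATF4 and amino acid stress had a median of 0.05 (percentile 76.9), with Ddit4 at 1.46, Nupr1 at -0.60, Vldlr at 0.52 and Mthfd2 at 0.46. Polyamine genes had a median of 0.23 (percentile 95.95, and 97.9 with normexp, where the list stood apart). Amd2 was at -1.56, Azin2 at 0.83, ornithine decarboxylase (Odc1) at 0.73 and Sat2 at 0.70. Azin2 was dim, its other probe gave 0.06, and with normexp Azin2 was at 0.26. Enzymes and readers of DNA methylation had a median of -0.03 (percentile 52.6), which crossed 0 under median, quantile, loess, spike-in and no scaling. The methyltransferase Dnmt3a was 1.64-fold lower, Tet2 was at 0.68, Dnmt1 at -0.53 and Tdg at 0.48.

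All 67 measured genes of the ribosomal protein list were higher on the cast array. Their median of 0.42 was above all 10000 random lists, and 10 of them were at least 1.5-fold higher. Rpl3 was at 1.55, and Rps25, Rpl21 and Rpl12 were at 0.83, 0.78 and 0.74. The probe of Rpl21 was dim, its second probe gave 0.26, and with normexp Rpl21 was at 0.46.

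Stress-responsive transcription differed by list. Immediate early genes were above 0 in 20 of 21 cases, with a median of 0.58, above all 10000 random lists, and Fos, Ccn1, Fosb and Junb had log2 ratios of 2.93, 1.38, 1.35 and 1.12. Glucocorticoid responsive genes had a median of 0.55, also above all random lists, with 12 of 16 above 0. Mt2 was at 2.92, Lcn2 at 1.98, Mt1 at 1.80 and Angptl4 at -1.15. Mt1 and Mt2 also led the oxidative stress list, whose median was 0.07 (percentile 73.6), followed by the peroxiredoxin Prdx6 at -0.51 and Gpx4 at 0.43. Inflammatory and NF-kB genes had a median of 0.44, above all random lists, and 13 of 15 were above 0. The chemokines Ccl7 and Ccl2 were at 2.63 and 2.34, the TWEAK receptor Tnfrsf12a at 1.98 and Nfkb2 at 1.33.

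Interferon response genes were lower, with 19 of 20 below 0 and a median of -0.34 (percentile 0.33), which became 0.0021 with no scaling and 0.014 with spike-in scaling. Usp18, Isg15, Ifit3 and Ifit1 were at -0.78, -0.76, -0.75 and -0.55. The 20 genes are those measured on both arrays, so they leave out the chemokine Cxcl10, which was well above background on the cast array only. With detection on at least 1 array, the median of the list was -0.37 (percentile 0.17). Only 3 of the interferon genes were among the brighter genes, too few to call. Heat shock genes had a median of -0.16 (percentile 3.06, and 0.68 with quantile scaling, where the list stood apart), above 0 with no scaling or spike-in scaling, with Hsph1 at -1.07, Hspb3 at 1.05 and Cryab at -0.75. Hspa4 was at 0.64, and at -0.50 when its probes were averaged. Unfolded protein response genes had a median of -0.03 (percentile 43.9), above 0 with median, spike-in and no scaling. Canx was at 0.67, Ern1 at 0.46, Xbp1 at 0.35 and Sdf2l1 at -0.33, the last turning to 0.0073 and 0.019 with no scaling and spike-in scaling. Clock genes had a median of 0.13 (percentile 88.2) and went both ways, with Nr1d1 at 0.94, Bhlhe40 at 0.93 and Dbp at -0.71. Cell cycle genes had a median of 0.13 (percentile 92.0, and 97.6 with normexp, where the list stood apart), with Aurka at -1.58, Rrm2 at 1.19, Birc5 at 0.41 and Mki67 at 0.27.

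**Figure D3:**
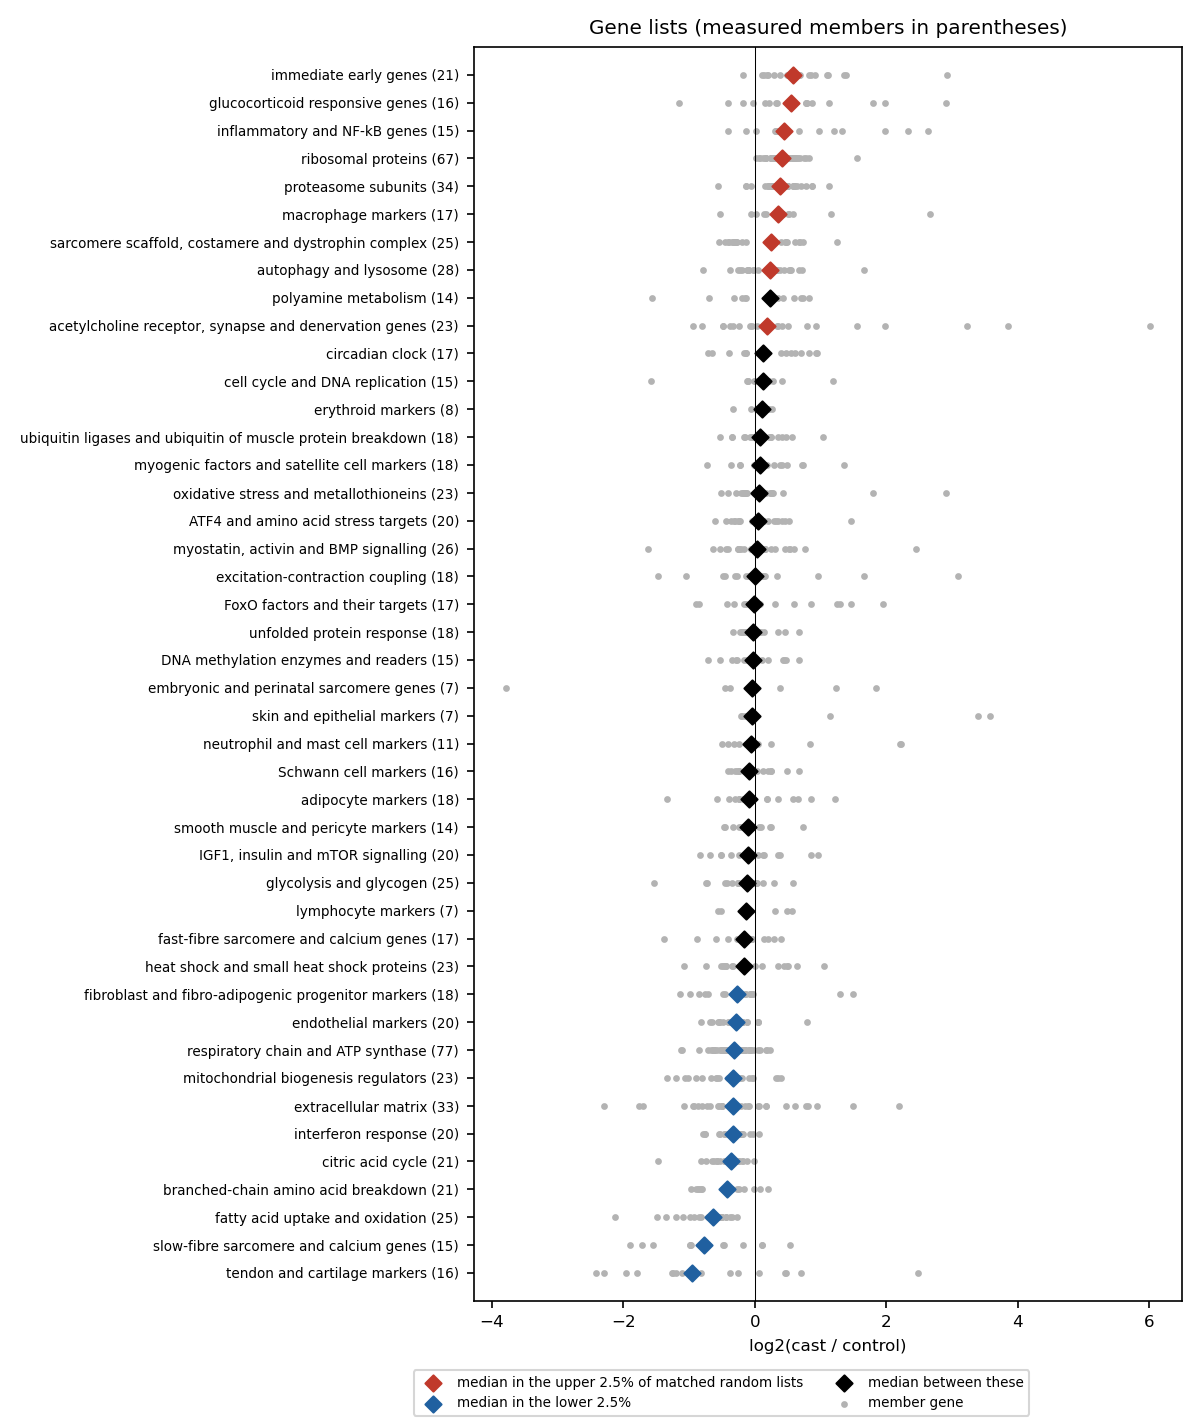
Log2(cast/control) of the measured members of each of the 44 gene lists (grey) and the list median (diamond), coloured where the median lies in the outer 2.5% of matched random lists on either side. Immediate early genes have the highest median, 0.58, and tendon and cartilage markers the lowest, -0.96. With no scaling or spike-in scaling every median moves up and those between -0.34 and 0 turn positive.

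Matrix and connective tissue genes split. The collagens Col1a1 and Col1a2, the main fibrillar collagen of tendon and bone, were at -1.76 and -1.70, and P4ha1, a collagen prolyl hydroxylase subunit, was at -2.30, whereas the protease inhibitor Timp1 was at 2.19. The extracellular matrix list had a median of -0.34, below all 10000 random lists, and of 0.0028 with no scaling and 0.014 with spike-in scaling. Of 33 members, 22 were below 0, 10 were at least 1.5-fold lower and 6 at least 1.5-fold higher. Tendon and cartilage markers had the lowest median of the 44 lists, -0.96, below all random lists, with 11 of 16 below 0. With normexp it was -0.45 and no longer the lowest. Kera was at -2.41, Ecrg4 at -2.30 and Chad at -1.97, and Cilp was at 2.48. Among the brighter genes alone, 9 members were left, with a median of -0.26 that no longer stood apart (percentile 3.37). Beside these values, fibroblast and fibro-adipogenic progenitor markers had a median of -0.27 (percentile 0.42), and of 0.064 and 0.075 with no scaling and spike-in scaling, and this list did not stand apart among the brighter genes (percentile 3.58). Their most distant members were lysyl oxidase (Lox, 1.49), Apod (1.29), Serpinf1 (-1.14) and Dpp4 (-0.98).

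Markers of other cell types were read as measures of what else the pools held. Macrophage markers were higher on the cast array, with 15 of 17 above 0 and a median of 0.35 (percentile 99.9). Lgals3 was at 2.66, Gpnmb at 1.15, lysozyme 2 (Lyz2) at 0.58 and Itgam at -0.53. Endothelial markers had a median of -0.29 (percentile 0.47), and of 0.051 and 0.062 with no scaling and spike-in scaling. Aplnr was at -0.82, Cldn5 at 0.79, Emcn at -0.68 and Sox18 at -0.65. The neutrophil and mast cell list had a median of -0.05 (percentile 53.1), but S100a9, S100a8 and Retnlg were at 2.23, 2.21 and 0.84, and the mast cell protease Mcpt4 was at -0.50. The skin and epithelial list had a median of -0.05 (percentile 52.8) over 7 measured members, or of 0.82 (percentile 99.98) with the mean of probes, where it stood apart, 3 of them at least 2-fold higher, with Krt18 at 3.58, Krt8 at 3.40 (2.56 and 1.52 with normexp) and Perp at 1.15, and the skin keratin Krt10 at -0.21. Both of these medians crossed 0 under median, quantile, loess, spike-in and no scaling, and Krt10 was at 0.13 and 0.14 with no scaling and spike-in scaling.

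The remaining cell type lists lay between the outer percentiles. Lymphocyte markers had a median of -0.13 (percentile 31.3), smooth muscle and pericyte markers of -0.10 (percentile 19.2), adipocyte markers of -0.09 (percentile 22.9) and Schwann cell markers of -0.09 (percentile 41.3), and all 4 medians lay above 0 with no scaling or spike-in scaling. Erythroid markers had a median of 0.11 (percentile 74.3). Cd52 was at 0.57, Nkg7 at -0.56 and Ptprc at 0.49 among lymphocyte markers. Besides Des, the smooth muscle list held Cspg4 at -0.47, Smtn at -0.46 and Higd1b at -0.33, the last close to 0 at 0.0074 and 0.019 with no scaling and spike-in scaling. Dgat2 was at -1.33, Scd1 at 1.21, Retn at 0.86 and Car3 at 0.66 among adipocyte markers. Egr2 was at 0.67, Mbp at 0.48 and S100b at -0.41 among Schwann cell markers. Bpgm was at -0.34, and at 0.0019 and 0.013 with no scaling and spike-in scaling, while the alpha-globin Hba-a1 was at 0.21 and Alas2 at 0.16.

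Background correction by normexp brought the ratios of several dim genes closer to 0 by over 1.5-fold. With it, Runx1 was at 1.72, Ccl2 at 1.52, Ccl7 at 1.09, S100a8 at 1.32, Timp1 at 1.53, Lox at 0.70, Gpnmb at 0.54, Junb at 0.29 and Retnlg at 0.07, and on the lower side Ecrg4 was at -1.52 and Bmp7 at -0.70. The brighter gene Sypl2 was at -0.78 with normexp, and its second probe gave -0.84 without it.

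In all, 20 of 44 lists stood apart from matched random lists, 11 lower and 9 higher, where 5 in 100, or 2.2, would do so by chance if the genes of a list varied independently, which they do not. A further 1103 genes were well above background on the control array only and 211 on the cast array only. The larger number on the control side goes with the higher threshold on the cast array, and bounds of at least 2-fold were nearly even, 82 and 78. Measured on the cast array only, the olfactory receptor Olfr1061 was at least 10.5-fold higher and the potassium channel Kcnn3 at least 7.33-fold. The chemokine Cxcl10 was 9.91-fold higher and the named probe of Ccdc136 22.3-fold. For Cxcl10 and Ccdc136, the control signals of -4.73 and -4.70 lay above the lowest one called well above background, -4.88. Their folds are thus plain ratios to a dim signal and not lower limits. The Ccdc136 fold holds for that probe only. A probe without a symbol that the file describes as the same gene was well above background on both arrays and 8.27-fold higher. On the control array only, Foxr1 was at least 9.62-fold lower in the cast pool, Prr15l at least 9.39-fold, Defb23 at least 7.94-fold and Rsph1 at least 6.88-fold. Of 39429 probes, 39030 had 1 spot, so a fold of a gene measured on 1 array only can rest on a single bright spot. Whether a fault of that spot or signal from another transcript plays a part was not tested.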

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

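Probes without a gene symbol entered none of the comparisons of genes, and a signal in them is therefore given here. Of 2811 such probes well above background on both arrays, 73 were at least 2-fold higher on the cast array and 42 at least 2-fold lower. Probe A_52_P423810, annotated on the array as a transcript of metallothionein-1, had a log2 ratio of 2.98, beside 1.80 for Mt1. Probe A_51_P135732, described as Ccdc136, a gene whose named probe was well above background on the cast array only, was at 3.05. Probe A_66_P101251, a transcript of charged multivesicular body protein 3, was at 2.72 but dim on the control array, at a level of -4.07. Probe A_52_P185343, a transcript of G-alpha-13, was at 2.52. Among the lower ones, probe A_51_P485421 of the immunoglobulin M heavy chain was at -2.31. With 1 array per group, these differences were not tested.

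For 3 patterns, explanations were weighed, and every test here was chosen only after the result it bears on had been seen.

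Slow-fibre genes and oxidative genes were lower on the cast array. Less slow tissue in the cast pool, through how the muscles were cut or pooled, stayed open for the slow list and the oxidative lists, with Myh7 at -0.77. That 3 members, Myl3, Myl2 and Csrp3, lay below Myh7 by more than 2 spot-level SD does not exclude it, since the spread between pools is unknown. For the slow list, a trend with signal was not the cause, with a median of -0.81 after loess, nor was scaling, with -0.42 on the spike-ins. For the respiratory chain, mitochondrial biogenesis and citric acid cycle lists, the medians on the spike-ins were 0.03, 0.019 and -0.02. Whether these lists were lower on an absolute scale could therefore not be told. A constant does not change their place below other genes, and with quantile or loess scaling their percentiles were at most 0.06.

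Tendon and cartilage markers and type I collagen were lower. Less tendon in the cast pool would lower every tendon transcript, and 4 markers, Cilp, Prg4, Scx and Thbs4, were higher by more than 2 spot-level SD, but that SD leaves out the spread between pools, so less tendon stayed open. The fibroblast list was lower by less than type I collagen, at -0.27 against a mean of -1.73 for Col1a1 and Col1a2. Since the spread between pools is unknown, this does not exclude fewer fibroblasts either. Lower matrix synthesis in the unloaded limb may apply as well, and the arrays hold no value that parts these explanations.

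All 67 measured genes of the ribosomal protein list were higher. A trend with signal was not the cause, as the median after loess was 0.35. A larger share of all non-muscle cells alike would raise the markers of most other tissues. Of 11 such lists, 2 had a median above that of all genes, or 4 of 11 with quantile or loess scaling. A larger share of a single cell type would raise the markers of that type alone. The count therefore cannot decide, and a larger share of non-muscle cells stayed open. A response of muscle cells to the cast, or of the cell types whose markers were higher, may apply, and neither was tested.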

How the results depend on the processing

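With 1 pooled array per group, the spread between mice is unknown, and no replicate could be left out and no slide blocked on. No paired analysis was possible because each group was a single pool. Dim genes are limited by the background, since 60.6% and 56.8% of probes were well above it. Leaving out saturated probes changed nothing because there were none, and keeping outlier spots added only 2 and 9. The number of lists standing apart ranged from 17 to 22 over the settings. Where no other cause is given the cause was not tested.

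The counts of genes at least 2-fold higher and lower became 826 and 119 with no scaling, 855 and 117 with spike-in scaling, 184 and 147 with normexp, whose offset shrinks ratios of dim probes, 749 and 871 with no filter, and 137 and 123 among the brighter genes. With detection on at least 1 array, 533 were lower. By construction, 1058 and 1238 passed 1.5-fold and 103 and 64 passed 3-fold. The spot-level SD, which adds up the spread within each array, was 0.25 with normexp against 0.10. Taken over differences at the same spot it was 0.05 and 0.06, so the excess was shared by both arrays and cancels in ratios.

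No scaling and spike-in scaling add a constant to every gene. List medians then turned positive for the respiratory chain (0.020 and 0.032), mitochondrial biogenesis (0.0073 and 0.019), extracellular matrix (0.0028 and 0.014) and interferon (0.0021 and 0.014). The same held for the endothelial (0.051 and 0.062) and fibroblast lists (0.064 and 0.075). A constant leaves every percentile as it was, so the unchanged percentiles are no check of these scalings. The sarcomere scaffold median became -0.013 with the mean of probes.

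The heat shock list stood apart at percentile 0.68 with quantile scaling, 2.15 with loess and 2.29 with the mean of probes. The sarcomere scaffold list did not at 97.0 with loess, 37.6 with the mean of probes, 64.4 without its largest member, 66.4 without shared members and 98.9 with outer bounds of 0.5%, which also ended the calls for autophagy (99.3) and denervation (98.8). Polyamine genes stood apart with normexp (97.9) and unmatched lists (98.1), cell cycle genes with normexp (97.6) and the skin list with the mean of probes (99.98). Among brighter genes, embryonic sarcomere (1.83) and myogenic genes (99.05) were gained, and fibroblast (3.58) and tendon lists (3.37) were lost. The interferon list (7.49) had only 3 members there, too few for a call.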

Other observations

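Skeletal muscle has its own form of the ribosomal protein Rpl3, called Rpl3l. The genes in this part were chosen after the values were seen. Rpl3 was 2.93-fold higher on the cast array, while Rpl3l was 1.30-fold lower. The log2 ratio of Rpl3l, -0.38, is close in size to the shift of 0.34 with no scaling and 0.35 with spike-in scaling. Rpl3l therefore hardly differed under those scalings, whereas Rpl3 was at 1.89 and 1.90.

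The keratins of simple epithelia and of the muscle cytoskeleton, Krt18 and Krt8, were 11.9-fold and 10.6-fold higher from dim control levels of -2.78 and -4.71, and with normexp their log2 ratios were 2.56 and 1.52 instead of 3.58 and 3.40.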
